A study of Mus musculus with 33 samples.

How the data were processed

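Gene expression was measured by RNA sequencing in 33 libraries, 3 in each of 11 sorted or whole cell groups of adult mouse bone marrow, and listed in 4 tables, each library in a column of its own. The deposited values are FPKM per gene, made by the authors. The processing notes of the submitters (the authors) name bcl2fastq 2.19.1.403, TopHat2 2.1.1, HTSeq 0.6.1, DESeq2 1.18.1 and the build mm10, per the labels. Per the labels, BMC and Lin- were prepared with a stranded total RNA kit and the other groups with a full-length poly(A)-primed kit (SMART-Seq v4 and Nextera XT). The tables were normalized separately, so groups of different tables were not tested gene by gene. The exceptions are the difference of the irradiation and Vav1 DTX contrasts, which compares log2 differences formed within tables, and the levels of Apln and other tip genes, which were compared across tables.

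Each table held 38926 genes and 0 columns without a sample; 27 gene names turned into dates in 3 of the tables were left out, which leaves 38899 genes in all 4. For each of these genes (100%) the values in the 33 libraries were whole multiples of a unit within a tolerance of 0.005, which gives the reads behind them, 1.57 to 12.44 M (mega) per library. The total by which the values had been divided differed from these reads, with ratios of 0.683 to 1.183. Of 38926 symbols, 35656 were found in GENCODE vM21 on GRCm38, a copy whose build may differ from the annotation the authors used, and the unit of 17881 genes was that of their exon length there. Positions are from that annotation, and 328 of 336 named genes were placed. Of the named genes 92 overlap another gene, and reads of close paralogs (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Bglap and Bglap2, Hspa1a and Hspa1b, histone genes) cannot be assigned with certainty.

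Values were used as log2(FPKM + 1), with a pseudocount of 1, and genes with at least 1 FPKM in at least 3 of the 6 libraries of a comparison were tested. Differences were fitted with limma 3.58.1 (eBayes with trend) in R 4.3.3 with version 1.17.8 of data.table, and calls are genes at a Benjamini-Hochberg adjusted p below 0.05. The 8 comparisons were bone EC against LSK, Lin- and BMC, Lin- against BMC, irradiated bone EC against bone EC, Vav1 DTX EC against Vav1 control EC, Apln+ EC against diaphysis EC and 9Gy1D EC against Esm1+ EC; the difference of the irradiation and Vav1 DTX contrasts was fitted on their 12 libraries. The tests are two-sided. An exact permutation test of 3 against 3 libraries cannot go below 0.1, so no gene was tested that way.

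Groups of genes were tested with camera of limma, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 27 lists of a comparison. The lists were the pan-endothelial, sinusoidal, arterial, tip and angiogenic, niche factor, VEGF, Notch target, basement membrane and matrix, p53 target, cell cycle, interferon, inflammatory, glycolysis, cholesterol synthesis, immediate early and dissociation stress, stem and progenitor, erythroid, neutrophil, B lymphoid, monocyte and macrophage, megakaryocyte and platelet, mesenchymal stromal, osteoblast, mural, mitochondrially encoded, poly(A)-less RNA and sex-linked genes, and some genes stand in more than 1 list. The comparisons, lists, filter, tests, alternatives in the first group below and the rule for named genes were chosen before the data were examined.

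Named genes are 13 identity genes, the 10 largest differences in each direction of the 5 endothelial or stem cell comparisons (5 in the others) and up to 4 called members of each list, or up to 2 members if fewer than 2 were called. The largest differences were taken among genes that passed, whose groups did not overlap and whose higher group averaged at least 5 FPKM, without predicted genes and immunoglobulin or T cell receptor segments. Genes followed over all groups among the other observations were chosen after their values were seen.

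The alternatives fixed first were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, TPM, no trend, a replicate block, all libraries of a table fitted together and leaving out each library. Added after the data were seen were limma voom on the recovered reads, scaling each library to its mean pan-endothelial level, averaging Esm1+ replicates 1 and 2, a replicate block with an estimated correlation, and median-of-ratios scaling over all 33 libraries for levels. A test made for counts was not used for the calls because the deposited values are not counts.

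The pipeline was tested on simulated data with the spread of each comparison. Changes of 1 on the log2 scale were found in 7% to 72% of genes and changes of 2 in 65% to 98%, both lowest in the difference of the irradiation and Vav1 DTX contrasts, and from 3.8% to 22% of calls were false, the highest in bone EC against LSK. Few genes were changed, all with many reads, and no shift in cell content was simulated. These shares therefore need not hold for the real calls or for genes with few reads. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Splicing, allele and transgene reads were not analysed here. Some named genes are not reported here.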

Results

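RNA was sequenced from 33 libraries of adult mouse bone marrow cell populations (C57BL/6, 8 to 12 weeks of age), 3 libraries in each of 11 groups. Of these groups, 3 held blood-forming cells of femur and tibia: whole bone marrow cells (BMC), lineage-negative cells (Lin-) and Lin- Sca1+ cKit+ cells (LSK), the fraction that holds the blood stem cells. The other 8 groups were sorted endothelial cells (EC). Bone EC, irradiated bone EC, diaphysis EC and 9Gy1D EC were GFP+ cells of Cdh5-mTnG reporter mice, irradiated bone EC and 9Gy1D EC after 9 Gy of irradiation and diaphysis EC from the femur shaft. Apln+ EC and Esm1+ EC came from tamoxifen-treated mice with an Apln-CreERT2 or an Esm1-CreER allele and a reporter. The Vav1 control EC and Vav1 DTX EC groups carried the same genotype, Vav1-Cre R26-DTR Cdh5-mTnG, and the same diphtheria toxin treatment in their labels, so that only their titles and column names tell them apart. The labels gave no time after irradiation, and the meaning of 9Gy1D and DTX was taken no further than the labels go.

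The reads behind the values, recovered from the steps of the deposited FPKM, ran from 1.57 to 1.89 M reads (M, mega) in the LSK libraries, 2.75 to 3.29 M in bone EC and 3.17 to 3.71 M in irradiated bone EC. They ran from 5.12 to 5.74 M in BMC, 5.32 to 6.42 M in Lin-, 5.61 to 6.19 M in 9Gy1D EC and 7.32 to 8.06 M in Esm1+ EC. The deepest libraries were those of Vav1 control EC (8.7 to 10.29 M), Apln+ EC (8.86 to 10.17 M), diaphysis EC (9.54 to 10.9 M) and Vav1 DTX EC (9.9 to 12.44 M). LSK libraries held 14925 to 18109 genes at 1 FPKM or more although they were the shallowest, against 12785 to 12878 in bone EC. The labels do not say whether the replicates are separate animals, so each p measures the spread between samples. Values below are mean FPKM ± SD with n = 3 per group, fold changes are ratios of these means, and log2 differences are on the log2(FPKM + 1) scale, which understates low genes.

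Cdh5, which encodes the endothelial junction protein VE-cadherin and drives the reporter of 6 of the groups, was at 81.5 ± 15.5 FPKM in bone EC and at 191 ± 10.3 in irradiated bone EC. It was at 0.243 ± 0.132 in LSK, 2.29 ± 0.61 in BMC and 6.89 ± 3.77 in Lin-. In the other endothelial groups, whose tables were normalized separately, it ran from 18.1 ± 3.48 in Esm1+ EC to 61.2 ± 14.5 in 9Gy1D EC. Transcripts of blood cells were abundant in the sorted endothelial libraries. The neutrophil gene S100a8 was at 18500 ± 1090 FPKM in bone EC and 73.6 ± 31.9 in LSK. Ptprc, the pan-leukocyte gene for CD45, was at 55.2 ± 15.5 FPKM in bone EC, 15.1 ± 3.56 in irradiated bone EC, 26.9 ± 9.22 in Vav1 DTX EC and 83.9 ± 1.06 in Esm1+ EC. The 16 neutrophil genes took 10.8% ± 0.504 of the FPKM sum in bone EC, 0.591% ± 0.478 in irradiated bone EC and 17.6% ± 0.846 in Esm1+ EC. The 18 pan-endothelial genes took 0.319% ± 0.0412, 1.03% ± 0.182 and 0.197% ± 0.0624 in these same groups. Cdh5 (ENSMUSG00000031871.9) lies on chromosome 8 from 104101625 to 104144511. S100a8 (ENSMUSG00000056054.9) on chromosome 3 from 90668978 to 90670035, both protein-coding genes on GRCm38.

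**Figure D1:**
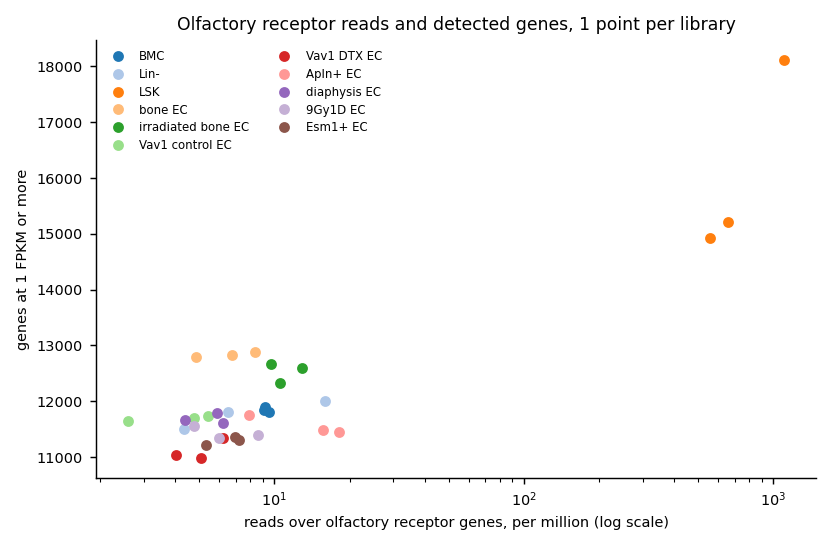
Reads over olfactory receptor genes per mega-read (RPM, log axis) against the number of genes at 1 FPKM or more, with 1 point per library of the 11 groups. LSK libraries lie at 557 to 1100 RPM and 14925 to 18109 genes, and the libraries of the other groups at 18.2 RPM or less.

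**Figure D2:**
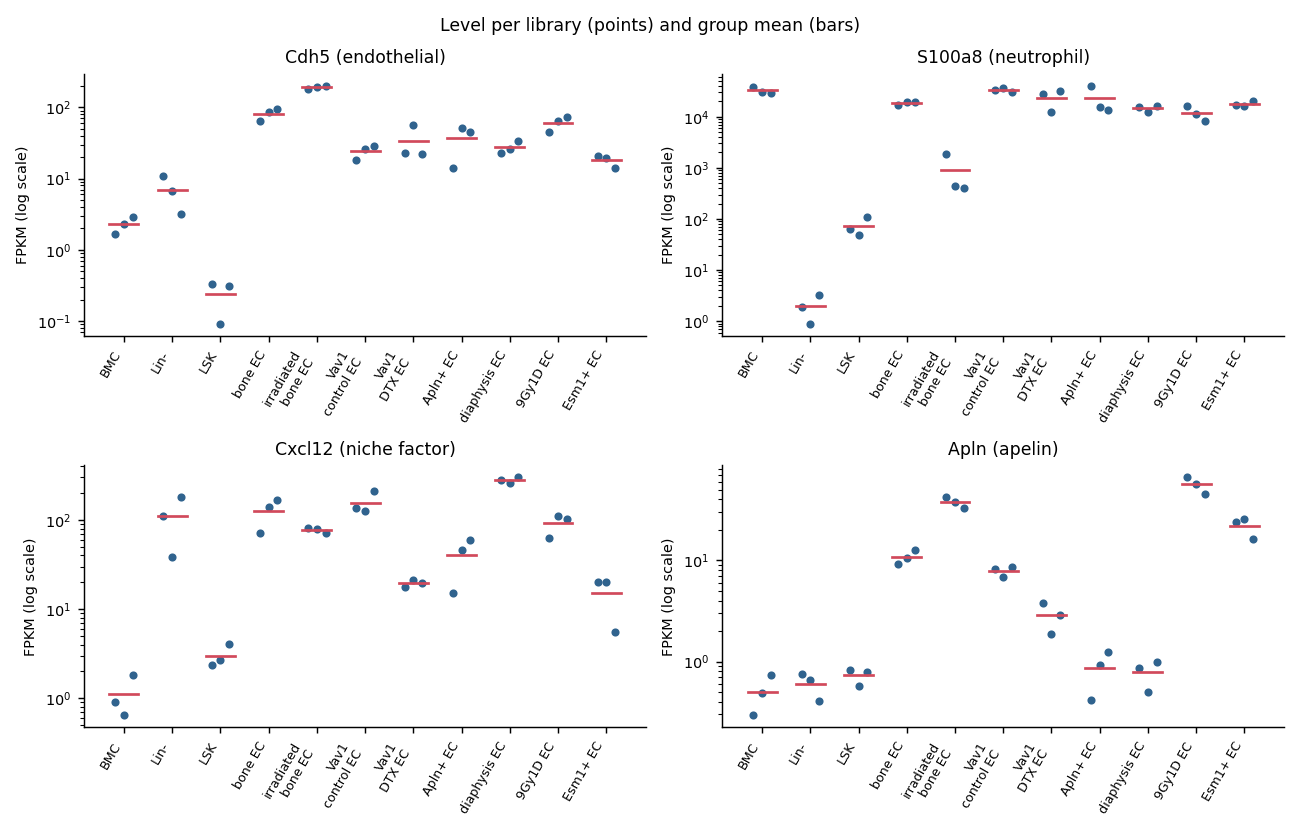
Level of Cdh5, S100a8, Cxcl12 and Apln (FPKM, log axis) in each library of the 11 groups; points are libraries and bars are group means, with tables normalized separately. S100a8 is at 18500 FPKM on average in bone EC, and Apln stays between 0.419 and 1.24 in the libraries of Apln+ EC and diaphysis EC.

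Bone EC against LSK asks what marks the endothelial cells apart from the stem and progenitor cells of the same marrow. Bone EC were higher in Fabp4, a fatty acid carrier of capillary endothelium (2090 ± 552 against 1.04 ± 0.315 FPKM), in Plvap, which forms the diaphragms of fenestrae (815 ± 115 against 1.4 ± 0.567), and in Kdr, the main VEGF receptor (83.7 ± 12.4 against 0.943 ± 0.442). LSK were higher in the stem cell transcription factor Hlf (30.8 ± 0.982 against 0.453 ± 0.0736 in bone EC), Kit (90.4 ± 12.9 against 6.02 ± 0.789) and Angpt1, the ligand of the receptor Tie2 (78.6 ± 3.79 against 1.87 ± 0.516). The neutrophil genes Ngp (log2 difference 8.41, SE 0.2, adjusted p = 1.2e-07) and Camp (7.9, SE 0.13, adjusted p = 7.3e-08) stood among the largest differences, next to Fabp4 (9.98, SE 0.22, adjusted p = 1.2e-07). Others at the top on the LSK side were Zfp488 (126 ± 45.5 against 2.18 ± 0.58 FPKM), Nkx2-3 (40.8 ± 5.73 against 0.182 ± 0.0698) and the vomeronasal receptor Vmn1r58 (45.9 ± 12.2 against 0.707 ± 0.353). Vomeronasal receptor genes took 317 to 585 RPM in the LSK libraries and at most 7.33 in any other, so that calls on the LSK side include genes not known to be active in blood cells.

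Of the endothelial lists, 17 of 18 pan-endothelial, 9 of 9 sinusoidal, 13 of 15 arterial and 14 of 16 tip and angiogenic genes were higher in bone EC, the same numbers when adjusted over the list alone. Examples are Cldn5 of tight junctions (216 ± 32.6 against 0.365 ± 0.318 FPKM), the mannose receptor Mrc1 of sinusoids (44.2 ± 6.17 against 0.505 ± 0.199) and the arterial gap junction gene Gja4 (14.1 ± 2.73 against 0.565 ± 0.569). All 15 basement membrane and matrix genes were higher, Sparc (981 ± 233 against 1.7 ± 0.392) and Col4a1 (128 ± 2.81 against 6.82 ± 0.66) among them, as were 15 of 19 niche factors, including Cxcl12, the chemokine that holds stem cells in the marrow (127 ± 50.1 against 3.01 ± 0.896). Of 9 VEGF ligands and receptors 7 were higher. Of 4 Notch targets, Dll4 was higher (19.1 ± 0.553 against 1.57 ± 0.666) and Hey1, Hes1 and Nrarp were lower. Set tests with a preset correlation called the pan-endothelial (adjusted p = 9.7e-11), sinusoidal (9.6e-08), tip (4.9e-07), matrix (1.4e-09), arterial (0.00049), niche (0.00037) and VEGF lists (0.0056). With an estimated correlation these gave adjusted p = 0.14, 0.18, 0.12, 0.087, 0.089, 0.18 and 0.16.

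Markers of mature blood cells went the same way: 16 of 16 neutrophil, 13 of 13 erythroid, 11 of 12 monocyte and macrophage and 9 of 12 B lymphoid genes were higher in bone EC. Lyz2 of myeloid cells was at 6190 ± 734 against 145 ± 14.1 FPKM, the globin gene Hba-a1 at 11000 ± 1040 against 737 ± 134 and the B cell receptor gene Cd79a at 148 ± 42.4 against 2.82 ± 1.68. Among the 27 lists in 9 contrasts the neutrophil list here was alone in keeping its call with an estimated correlation (adjusted p = 0.039, against 8.7e-12 with the preset). In bone EC against LSK the number of lists so kept was 0 with the replicate block or a minimum mean of 5 FPKM, 8 with TPM and 9 with no filter. The erythroid (9.7e-09), monocyte and macrophage (1.5e-06) and B lymphoid lists (7e-04) gave adjusted p = 0.056, 0.12 and 0.39 with an estimated correlation. Of 15 stem and progenitor genes 11 were lower in bone EC and 2 higher (adjusted p = 0.00021, and 0.087 with an estimated correlation).

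Further lists called were the interferon response (14 of 20 higher, adjusted p = 0.00049, and 0.38 with an estimated correlation), mesenchymal stromal (7 of 9 higher, 8 when adjusted over the list alone, adjusted p = 0.0094 and 0.5), mural (5 of 5 higher, 0.0022 and 0.18), osteoblast (2 of 2 higher, 0.035 and 0.2) and RNAs without a poly(A) tail (5 of 7 higher, 7 when adjusted over the list alone, 0.03 and 0.48). Adipoq of marrow adipocytic stroma was at 49.8 ± 20.5 against 0.554 ± 0.427 FPKM and the bone matrix gene Ibsp at 75.7 ± 36.6 against 1.15 ± 0.484. The cell cycle (11 higher, 10 lower of 30), p53 target (7 and 3 of 20), inflammatory activation (9 and 5 of 18), glycolysis (5 and 4 of 14), cholesterol synthesis (4 and 5 of 16), megakaryocyte and platelet (3 and 1 of 8), mitochondrially encoded (3 and 0 of 12) and sex-linked lists (1 and 4 of 5) were not called. After rescaling to TPM, the medians of the cell cycle, p53, inflammatory, glycolysis, megakaryocyte and mitochondrial lists turned from 0.2, 0.22, 0.7, 0.08, 0.3 and 0.48 to -0.49, -0.32, -0.33, -0.61, -0.09 and -0.22. The immediate early and dissociation stress list had a median of -0.2 and a mean of 0.09, with 4 of 14 genes higher and 4 lower.

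Of 14321 genes tested, 8608 passed, 4219 higher and 4389 lower in bone EC; 2487 and 2232 of these differed more than 2-fold, and 66.5% of tested genes had groups that did not overlap, against 10% by chance. Of the genes lower in bone EC, 1786 (40.7%) had an LSK mean under 5 FPKM. Rescaling to TPM shifted the median gene by -0.68 and gave 13810 calls, 17.6% of them higher in bone EC, against 49% as deposited; a minimum mean of 5 FPKM left 5083 calls.

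Against Lin-, prepared with a total RNA kit, bone EC were higher in neutrophil genes such as S100a8 (18500 ± 1090 against 2.02 ± 1.22 FPKM) and Ngp (7250 ± 1050 against 1.24 ± 0.341). They were higher in endothelial genes such as Plvap (815 ± 115 against 14.4 ± 5.97) and Cldn5 (216 ± 32.6 against 3.71 ± 2.52). Lin- were higher in Col1a1, the main collagen of bone (1190 ± 762 against 5.05 ± 4.34), in the osteocalcin gene Bglap (350 ± 208 against 2.28 ± 2.27, its reads uncertain against those of its paralog Bglap2) and in the platelet chemokine Pf4 (500 ± 135 against 76.8 ± 22.7). All 12 RNAs without a poly(A) tail were higher in Lin-, including Rn7sk (32600 ± 2690 against 10.7 ± 3.71) and Rmrp (6660 ± 1720, and listed at 0 in bone EC), as they were in BMC. The 2 library kits differ with this contrast and cannot be separated from it. The set test gave adjusted p = 4.3e-08 for that list, and 0.29 with an estimated correlation.

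Higher in bone EC than in Lin- were 17 of 18 pan-endothelial, 9 of 9 sinusoidal, 10 of 14 arterial, 13 of 16 tip, 12 of 15 matrix, 17 of 20 interferon and 15 of 16 neutrophil genes, and 17, 9, 11, 13, 12, 18 and 16 when adjusted over the list alone. Lower were 9 of 9 megakaryocyte and platelet, 8 of 12 mesenchymal stromal, 6 of 7 osteoblast, 18 of 30 cell cycle and 11 of 16 stem and progenitor genes. Called with the preset correlation were 19 of 27 lists, 13 up and 6 down, and the lowest adjusted p of any list was 0.29 with an estimated correlation. The erythroid list had a median of 1.99 and a mean of 1.64 while its test pointed down, and 3 of its 13 genes passed, all lower, such as Car1 (110 ± 17.7 against 1120 ± 81.3 FPKM). Lin- replicate 3 stood apart in erythroid genes, with Hbb-bs at 73, 83.4 and 38900 FPKM in replicates 1 to 3, and without it the test of that list pointed up (adjusted p = 0.057). Of 13255 genes, 8822 passed, 4746 higher and 4076 lower. Groups lay apart for 72% of genes against 10% by chance; TPM shifted the median gene by 0.19. A minimum mean of 5 FPKM left 5624 calls. Sex-linked genes differed with this contrast, 1 higher and 4 lower of 5: Xist was at 7.05 ± 3.04 against 0.00402 ± 0.00696, and the Y-linked Ddx3y at 0.0589, 6.55 and 2.91 in the bone EC libraries against 12 ± 2.16 in Lin-.

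Bone EC against BMC again separated endothelial genes from the mixed marrow: Plvap was at 815 ± 115 against 0.392 ± 0.487 FPKM, Igfbp7 at 690 ± 131 against 0.839 ± 0.621 and the sinusoidal scavenger receptor Stab2 at 43.6 ± 4.59 against 0.224 ± 0.0852. Cldn5 was listed at 0 in BMC. BMC were higher in the neutrophil gene S100a9 (37300 ± 5930 against 13600 ± 736) and the recombinase gene Rag1 of B cell precursors (49.4 ± 12.7 against 1.82 ± 0.757). Bone EC in the complement gene C1qb of macrophages (141 ± 4.12 against 6.29 ± 1.62). Here 17 of 18 pan-endothelial, 9 of 9 sinusoidal, 13 of 14 arterial, 14 of 16 tip, 14 of 15 matrix, 9 of 12 monocyte and macrophage and 10 of 13 erythroid genes were higher, the same when adjusted over the list alone. Lower were 14 of 16 neutrophil, 10 of 12 B lymphoid and 18 of 30 cell cycle genes (cell cycle median -0.39, and 0.01 after rescaling to TPM), and 19 lists were called (15 up, 4 down), with a lowest adjusted p of 0.23 with an estimated correlation. Of 13194 genes, 9287 passed, 4722 higher and 4565 lower. BMC, like Lin-, were prepared with the total RNA kit, so kit and population cannot be told apart here either. For 74.7% of genes the groups did not overlap. TPM shifted the median gene by 0.41 and raised the share of higher calls from 50.8% to 69.3%. A minimum mean of 5 FPKM left 6069 calls.

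Genes higher in bone EC than in each of LSK, Lin- and BMC numbered 1854 of 12375 tested in all 3 contrasts, which share the bone EC libraries. Of these 929 were more than 2-fold and 145 more than 8-fold higher each time. They included 17 of 18 pan-endothelial, 9 of 9 sinusoidal, 12 of 16 tip and 12 of 15 matrix genes, 8 of 12 monocyte and macrophage genes and 10 of 20 interferon genes, and 0 of 30 cell cycle, 0 of 16 neutrophil and 0 of 13 erythroid genes. Without bone EC replicate 1, 2 or 3 the count was 969, 791 or 735.

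Lin- against BMC shows what lineage depletion left. Sex was not balanced between them: Ddx3y was at 0, 0.0471 and 17.5 FPKM in the BMC libraries and at 12 ± 2.16 in Lin-. Neutrophil genes were lower in Lin-, S100a8 at 2.02 ± 1.22 against 32900 ± 5110 FPKM, and so was the B cell gene Ms4a1 (0.423 ± 0.269 against 62.9 ± 16.4). Higher were the cartilage collagen Col2a1 (531 ± 266 against 1.63 ± 1.19), Col1a1 (1190 ± 762 against 5.39 ± 3.98), Cxcl12 (110 ± 70.8 against 1.12 ± 0.615), the platelet gene Ppbp (283 ± 89.7 against 1.97 ± 2.15) and Kit (50.6 ± 8.92 against 12.9 ± 1.03). All 16 neutrophil, 12 of 12 B lymphoid, 9 of 10 monocyte and macrophage and 13 of 21 interferon genes were lower, and 11 of 11 mesenchymal stromal, 7 of 7 osteoblast, 9 of 9 megakaryocyte, 11 of 13 matrix and 10 of 12 pan-endothelial genes higher, the same when adjusted over the list alone. Those 9 lists were the ones called with the preset correlation, none with an estimated correlation (lowest adjusted p 0.4). The arterial list (median -0.09, mean 0.06) and the erythroid list (median -0.69, mean -0.67, test pointing up) differed in sign between summaries. Of 12428 genes, 7144 passed, 3615 higher and 3529 lower. Groups lay apart for 66.1% of genes; TPM shifted the median gene by 0.22 and gave 60.9% higher calls against 50.6%.

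Irradiated bone EC against bone EC asks how endothelial cells respond to 9 Gy. Fgf23, a hormone of phosphate balance made in bone, was at 263 ± 14.4 FPKM after irradiation and 5.29 ± 1.86 in untreated cells (log2 difference 5.43, SE 0.22, adjusted p = 0.00013). It was higher in 3 of 3 libraries than in any untreated library, which the rule for the largest differences requires. The chemokine Cxcl9 rose from 15.1 ± 6.77 to 312 ± 56.6 (log2 difference 4.35, SE 0.29, adjusted p = 2e-04). The interferon-induced GTPase Iigp1 rose from 32.1 ± 7.65 to 475 ± 105 and the mucosal addressin gene Madcam1 from 2.05 ± 1.45 to 33 ± 10.8. Blood cell transcripts fell: the neutrophil elastase Elane from 417 ± 62.4 to 2.63 ± 1.56 (log2 difference -6.95, SE 0.35, adjusted p = 0.00016), Hba-a1 from 11000 ± 1040 to 141 ± 83.6, with reads uncertain against its paralog Hba-a2, and Vpreb3 of B cell precursors from 92.1 ± 23 to 1.76 ± 1.88. Fgf23 (ENSMUSG00000000182.9) lies on chromosome 6 from 127072902 to 127081408. Cxcl9 (ENSMUSG00000029417.9) on chromosome 5 from 92321347 to 92328079.

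Endothelial genes rose on the deposited scale: 17 of 18 pan-endothelial and 9 of 9 sinusoidal genes, the same when adjusted over the list alone, with list medians of 1.08 and 2.04, the first falling to -0.16 when each library was scaled to its mean pan-endothelial level. Stab2 rose from 43.6 ± 4.59 to 298 ± 110 FPKM, the lymphatic and sinusoidal VEGF receptor Flt4 from 32.9 ± 6.89 to 207 ± 79.4 and the adhesion molecule Vcam1 from 180 ± 25.5 to 1030 ± 176. Irradiated replicate 1 stood apart in cell content, with Stab2 at 178, 393 and 324 FPKM in replicates 1 to 3, Kdr at 178, 404 and 357, Lyz2 at 1010, 343 and 279 and Camp at 223, 47.5 and 36.7. Without it the log2 difference of Stab2 was 3.01 against 2.68 with it. The set tests gave adjusted p = 1.6e-07 and 7.2e-06, and 0.28 and 0.29 with an estimated correlation. Of 16 tip and angiogenic genes 9 rose, among them Angpt2, which loosens vessel walls (2.96 ± 0.93 to 27.2 ± 5.96), and 2 fell, Cxcr4 among them (52.7 ± 10.1 to 6.16 ± 2.94), with a median of 0.87 that turned to -0.35 under that scaling (adjusted p = 0.029, and 0.3 with an estimated correlation). Of 18 niche factors 9 rose and 2 fell (10 and 3 when adjusted over the list alone), with a median of 0.72 that turned to -0.33 (adjusted p = 0.042, and 0.33 with an estimated correlation). Selp rose from 38.9 ± 6.43 to 201 ± 27.7 and Il6 fell from 18.9 ± 0.823 to 3.27 ± 1.52. Not called were the arterial (7 up, 1 down of 15), VEGF (6 up of 9), Notch target (3 up of 4) and matrix lists (9 up, 1 down of 15), whose medians of 0.68, 0.7, 1.02 and 0.69 turned to -0.36, -0.43, -0.22 and -0.35. Nrp1, Dll4 and Hes1 were higher by 1.05, 1.02 and 1.03 as deposited and at -0.2, -0.2 and -0.22 under that scaling.

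Targets of p53 rose in 13 of 21 cases and fell in 2: Cdkn1a, which arrests the cell cycle, went from 69.8 ± 16.9 to 411 ± 66.6 FPKM, Phlda3 from 13.6 ± 4.18 to 108 ± 8.13 and the death receptor gene Eda2r from 0.151 ± 0.0925 to 5.03 ± 0.707. The list had adjusted p = 0.00051, and 0.26 with an estimated correlation, and its mean turned from 1.01 to -0.16 when scaled to the pan-endothelial genes. Of 21 interferon genes 18 rose, Cxcl10 from 21.3 ± 3.79 to 131 ± 34 among them, and 1 fell (adjusted p = 2.6e-06, and 0.26 with an estimated correlation), with a mean that turned from 1.09 to -0.12. Cell cycle genes fell in 29 of 30 cases as deposited, Mki67 from 18.5 ± 3.2 to 1.74 ± 1.17 and Ccna2 from 54.4 ± 3.23 to 6.52 ± 2.58 (adjusted p = 3.3e-15, and 0.26 with an estimated correlation). Scaling to the pan-endothelial genes also left 29, but it lowers the log2 differences of this comparison and could not have removed a fall. A smaller share of blood cell RNA was not separated from a fall within endothelial cells. Of 15 cholesterol synthesis genes 8 fell and 1 rose (adjusted p = 0.014, and 0.26 with an estimated correlation). The inflammatory list (10 up, 3 down of 18; Ptgs2, the inducible cyclooxygenase, fell from 34.7 ± 10.7 to 2.51 ± 0.672), glycolysis (2 up, 5 down of 14) and the immediate early list (6 up, 1 down of 14, median 0.45 turning to -0.8) were not called.

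Beside these, 13 of 13 erythroid, 16 of 16 neutrophil and 11 of 11 B lymphoid genes fell, with medians of -4.9, -4.61 and -3.45 (adjusted p = 5.2e-11, 2.6e-11 and 2.4e-08, each 0.26 with an estimated correlation). Of 12 monocyte and macrophage genes 5 fell and 1 rose, with a median of -0.34. Lyz2 fell from 6190 ± 734 to 545 ± 405 while C1qb was at 165 ± 103 against 141 ± 4.12. Megakaryocyte genes (6 of 7), stem and progenitor genes (8 of 12) and RNAs without a poly(A) tail (5 of 7, replication-dependent histone genes with shared reads) also fell, with adjusted p = 0.0023, 0.0013 and 0.001, and 0.26, 0.26 and 0.3 with an estimated correlation. Of 12 mitochondrially encoded genes 3 fell, 0 when adjusted over the list alone (adjusted p = 0.045, and 0.61 with an estimated correlation). Of 11 mesenchymal stromal genes 0 passed in limma. Adipoq was at 47.7 ± 25.9 against 49.8 ± 20.5. Mural genes rose in 3 of 6 cases, osteoblast genes were split (1 up, 1 down of 4, median 0.82 and test pointing down) and 0 of 3 sex-linked genes passed.

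Of 13044 genes, 5463 passed, 2938 higher and 2525 lower after irradiation, 1242 and 1543 of them by more than 2-fold. For 54.2% of genes the groups did not overlap against 10% by chance. TPM shifted the median gene by 0.25 and gave 67.2% higher calls against 53.8%. Scaling to the pan-endothelial genes, a choice made after the data were seen, shifted it by -1.09 and gave 9977 calls, 3.66% of them higher.

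**Figure D3:**
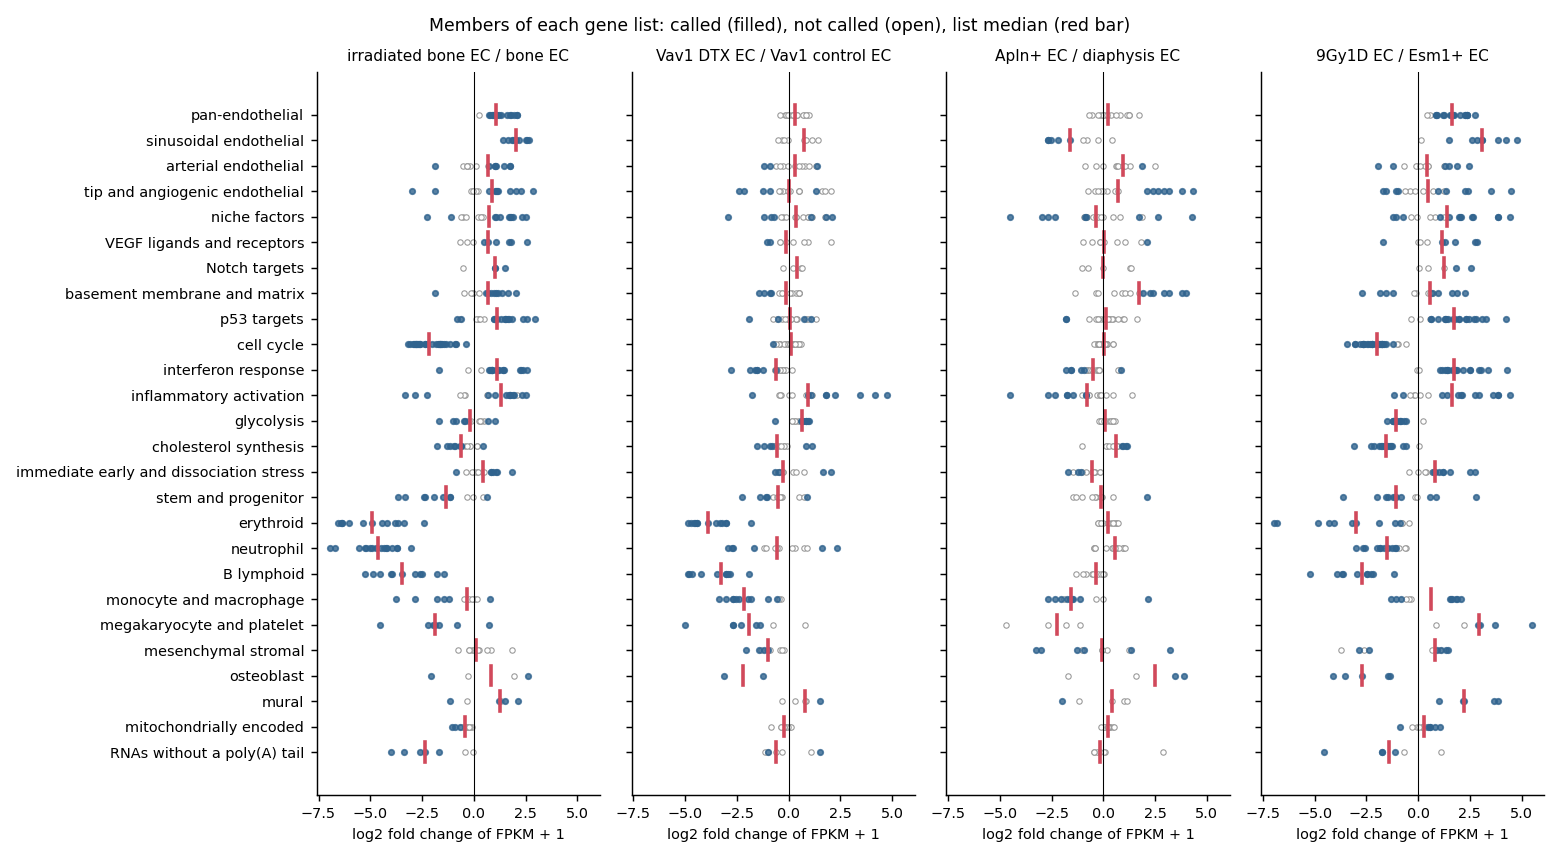
Log2 difference of each member of 26 gene lists in the 4 endothelial comparisons; filled points passed the test, open points did not, and red bars are list medians on the deposited scale. The sinusoidal median is 2.04 in irradiated bone EC and -1.62 in Apln+ EC; under scaling to the pan-endothelial genes the medians of the pan-endothelial, arterial, tip, niche, VEGF, Notch, matrix, immediate early and osteoblast lists turn below 0 in irradiated bone EC.

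Vav1 DTX EC against Vav1 control EC compares sorted endothelial cells whose labels name a Vav1-Cre R26-DTR genotype, meant to make blood cells sensitive to diphtheria toxin, in both groups. The columns are named Cont and Cre, so it is not certain that the control mice carry Cre. Cxcl12 fell from 157 ± 44.7 to 19.4 ± 1.76 FPKM (log2 difference -2.92, SE 0.2, adjusted p = 0.00016), Esm1, a tip cell proteoglycan, from 14.9 ± 2.97 to 1.99 ± 0.293 and Apln, the tip cell peptide apelin, from 7.83 ± 0.888 to 2.86 ± 0.965. Stromal and bone genes fell along with Cxcl12, which stromal cells make as well: in control replicates 1 to 3 Cxcl12 was at 136, 127 and 209, Adipoq at 48.7, 44.6 and 65.8 and Ibsp at 69.6, 62.6 and 117, and their log2 differences were -2.92, -2.08 and -3.14. A smaller share of stromal RNA was not separated from a fall within endothelial cells. Inflammatory genes rose: the acute phase gene Saa3 was at 807 ± 1060 against 4.19 ± 2.16 (adjusted p = 0.026), the granulocyte growth factor gene Csf3 at 122 ± 153 against 1.05 ± 0.393 (adjusted p = 0.019) and the monocyte chemokine Ccl7 at 94 ± 12 against 7.81 ± 0.81 (adjusted p = 5.9e-05). DTX replicate 2 stood apart, with Saa3 at 381, 2020 and 22.2 FPKM in replicates 1 to 3, Csf3 at 61.7, 296 and 8.15 and the endothelial gene Cldn5 at 213, 862 and 288. Without it the log2 difference of Saa3 was 4.29 (adjusted p = 0.016) against 5.76 with it, and that of Csf3 3.57 (adjusted p = 0.0065) against 4.78. B cell and erythroid genes fell, Cd79a from 209 ± 26.8 to 6.25 ± 0.99 and Alas2, the first enzyme of heme synthesis, from 965 ± 280 to 40.2 ± 13.2. Cxcl12 (ENSMUSG00000061353.11) lies on chromosome 6 from 117168535 to 117181367, Saa3 (ENSMUSG00000040026.8) on chromosome 7 from 46711998 to 46715700.

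Of 19 inflammatory genes 8 rose and 1 fell, 9 and 1 when adjusted over the list alone, and of 14 glycolysis genes 7 rose and 1 fell (8 and 1), with adjusted p = 0.02 and 0.0072, each 0.91 with an estimated correlation. Ldha of lactate production rose from 350 ± 24.1 to 643 ± 159 FPKM and Pgam1 from 62.3 ± 3.05 to 131 ± 40.6. Of 20 interferon genes 7 fell, Rsad2 from 132 ± 47.1 to 18.9 ± 8.89 and Irf7 from 53.1 ± 3.18 to 19.4 ± 10.1 (adjusted p = 0.00086, and 0.91 with an estimated correlation). All 13 erythroid, 10 of 10 B lymphoid, 10 of 12 monocyte and macrophage (11 when adjusted over the list alone) and 6 of 8 megakaryocyte genes fell, with adjusted p = 8.3e-13, 6.6e-12, 8.4e-08 and 0.0051, and 0.57, 0.28, 0.57 and 0.91 with an estimated correlation. Of 16 neutrophil genes 2 rose and 4 fell: Ctsg of early granule formation went from 211 ± 19.9 to 1190 ± 531, and Ly6g of mature neutrophils from 346 ± 32.5 to 47 ± 17.6. Mesenchymal stromal genes fell in 4 of 9 cases (5 when adjusted over the list alone) and osteoblast genes in 2 of 2 (adjusted p = 0.0077 and 0.042, and 0.59 and 0.71 with an estimated correlation). Adipoq went from 53.1 ± 11.3 to 11.9 ± 3.69 and Ibsp from 83.2 ± 29.9 to 9.48 ± 6.74.

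Not called were 18 lists, and 0 of 18 pan-endothelial and 0 of 9 sinusoidal genes passed in limma, with Plvap at 773 ± 258 against 858 ± 99.8 FPKM and Vcam1 at 341 ± 199 against 141 ± 22.7. Of 16 tip genes 4 fell and 1 rose (4 each when adjusted over the list alone; median and mean 0.04, test pointing down), and of 18 niche factors 4 fell and 3 rose (5 each). The other lists gave 1 up and 2 down of 13 arterial, 2 down of 9 VEGF (median -0.14, mean 0.11), 0 of 4 Notch target, 4 down of 14 matrix, 2 up and 2 down of 20 p53 target, 1 down of 30 cell cycle and 2 up and 4 down of 15 cholesterol genes. They also gave 2 up and 2 down of 14 immediate early (median -0.29, mean 0.08), 1 up and 4 down of 13 stem and progenitor, 1 up of 5 mural and 1 up and 1 down of 7 genes without a poly(A) tail; 0 of 12 mitochondrially encoded and 0 of 3 sex-linked genes passed. Of 11664 genes, 3065 passed, 1317 higher and 1748 lower (43% higher). Groups lay apart for 46.3% of genes against 10% by chance. TPM shifted the median gene by 0.25 and gave 67.3% higher calls. Scaling to the pan-endothelial genes shifted it by -0.26 and gave 1519 calls, 9.61% of them higher. The replicate block gave 34.8% higher. The count was 4764 without DTX replicate 2 and 1124, 1199 and 1194 without control replicates 1, 2 and 3.

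The irradiation contrast differed from the Vav1 DTX contrast, by a test of the difference itself, at 3684 of 13779 genes, 1883 with the higher log2 difference after irradiation and 1801 with the lower. The granule gene Ctsg of early neutrophils was at 1.03 ± 0.681 against 92.4 ± 19.6 after irradiation and at 1190 ± 531 against 211 ± 19.9 in Vav1 DTX EC (difference of log2 differences -7.93, SE 0.51, adjusted p = 1e-05). Apln rose with irradiation from 10.8 ± 1.85 to 37.9 ± 4.69 and fell in Vav1 DTX EC (2.95, SE 0.27, adjusted p = 9.5e-05). The complement gene C1qa of macrophages was at 83.5 ± 55.4 against 75 ± 3.52 and at 4.55 ± 2.46 against 54.1 ± 11.8 (3.35, SE 0.57, adjusted p = 0.0025). Cxcl12 differed by 2.3 (SE 0.4, adjusted p = 0.0026), at 77.1 ± 4.52 after irradiation and 19.4 ± 1.76 in Vav1 DTX EC against 127 ± 50.1 and 157 ± 44.7 in their controls. The stromal gene Adipoq was at 47.7 ± 25.9 and 11.9 ± 3.69 in these groups against 49.8 ± 20.5 and 53.1 ± 11.3. A change in stromal RNA was not separated from a change of Cxcl12 within endothelial cells.

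In this test of the difference 19 of 21 interferon genes (20 when adjusted over the list alone), 9 of 22 p53 targets (12), 7 of 18 pan-endothelial and 5 of 9 sinusoidal genes (6) were higher on the irradiation side, the pan-endothelial median of 0.83 turning to -0.11 when scaled to those genes. On that side 26 of 30 cell cycle (28), 14 of 16 neutrophil and 6 of 14 glycolysis genes were lower. The adjusted p values were 6.1e-11, 0.0013, 0.00066, 0.0015, 1.6e-16, 2.8e-12 and 0.027 with the preset correlation, and 0.35, 0.35, 0.6, 0.6, 0.35, 0.35 and 0.6 with an estimated correlation. Called lists numbered 14 (8 up, 6 down). The B lymphoid list was not among them (0 up, 1 down of 12, median 0.03, mean -0.14), nor were the cholesterol (median 0.01, mean -0.14) and mural lists (median and mean above 0, test pointing down). Of 11207 genes tested in both comparisons, 299 rose in both (277 if independent) and 915 fell in both (352 if independent). Another 124 rose with irradiation and fell in Vav1 DTX EC (368) and 114 did the opposite (265). Across these genes, which are not independent replicates, Pearson r of the log2 differences was 0.378 and Spearman rho 0.327. The number that moved the same way was 1214, and 585, 589 or 623 without Vav1 control replicate 1, 2 or 3. The test of the difference gave 2408 genes without irradiated replicate 3 and 2399 with the replicate block. Scaling to the pan-endothelial genes shifted its median by -0.76 and left 9.77% on the higher side against 51.1%.

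Apln+ EC against diaphysis EC sets cells marked by the Apln-CreERT2 allele beside all endothelial cells of the shaft. Genotype, tamoxifen and region (whole bone against shaft) differ together here, and sex-linked genes differ as well. No cause of a difference can therefore be named. Apln+ EC were higher in the endothelin receptor Ednrb (102 ± 56.9 against 2.04 ± 0.592 FPKM; log2 difference 4.88, SE 0.52, adjusted p = 0.0035), the adrenomedullin co-receptor Ramp3 (239 ± 145 against 5.93 ± 0.975), Cd34 (479 ± 258 against 24.3 ± 4.06) and the basement membrane collagen Col18a1 (33.6 ± 17 against 0.966 ± 0.0584). Diaphysis EC were higher in E-selectin Sele (88.7 ± 20 against 3.32 ± 2.42), Vcam1 (305 ± 57.3 against 48.9 ± 17.8) and Cxcl12 (281 ± 21.4 against 40.2 ± 22.7, log2 difference -2.98, SE 0.48, adjusted p = 0.016). Stromal cells make Cxcl12 as well, and the stromal genes Lepr and Adipoq differed by -3.26 and -3, while Col1a1 and Col1a2 went the other way (3.21 and 1.34). A larger share of stromal RNA in diaphysis EC was not separated from a difference within endothelial cells. Apln+ replicate 1 stood apart in cell content: Ednrb was at 36.3, 138 and 131 FPKM in replicates 1 to 3, Cldn5 at 119, 470 and 556 and S100a8 at 40100, 15600 and 13400. Without it the log2 difference of Ednrb was 5.5. Ednrb (ENSMUSG00000022122.15) lies on chromosome 14 from 103814625 to 103844402. Apln itself was at 0.865 ± 0.417 and 0.786 ± 0.258 FPKM, from 10 to 38 reads per library.

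Of 9 sinusoidal genes 5 were lower in Apln+ EC, Stab2 at 5.85 ± 3.03 against 36.4 ± 7.61 FPKM among them, while 7 of 15 tip genes and 7 of 15 matrix genes were higher (9 higher and 1 lower for matrix when adjusted over the list alone), such as Col4a1 (170 ± 96 against 15.5 ± 4.22) and Kcne3 (116 ± 75.3 against 3.8 ± 0.664). Their adjusted p were 0.00016, 0.0014 and 5.4e-05, each 0.59 with an estimated correlation. Lower in Apln+ EC were 8 of 18 inflammatory genes (9 when adjusted over the list alone), 3 of 14 immediate early genes (6), 5 of 21 interferon genes (7, with 1 and then 2 higher) and 8 of 12 monocyte and macrophage genes (9), with Cx3cr1 at 3.78 ± 3.04 against 25.4 ± 5.02 and Cd14 higher at 1430 ± 658 against 294 ± 3.25. Higher were 4 of 15 cholesterol genes (10 when adjusted over the list alone) and 1 of 13 arterial genes (2). These lists had adjusted p = 5.4e-05, 5.4e-05, 0.001, 4.6e-06, 5.4e-05 and 0.042, and 0.59 for the first 5 and 0.82 for the arterial list with an estimated correlation. The megakaryocyte list was called down (adjusted p = 0.023, and 0.59 with an estimated correlation) with 0 of 4 genes passing.

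Stromal and bone genes were split: Lepr of stromal cells (1.74 ± 0.652 against 25.3 ± 6.06 FPKM) and Adipoq (15.5 ± 9.79 against 109 ± 8.76) were lower in Apln+ EC and Col1a1 (11.8 ± 3.6 against 0.357 ± 0.18) and Bglap (18.3 ± 11 against 0.167 ± 0.29) higher, among 2 up and 4 down of 11 mesenchymal and 2 up of 4 osteoblast genes. Col2a1 was at 35.3 ± 37.8 and listed at 0 in diaphysis EC. The 4 sex-linked genes passed, Ddx3y higher (19.7 ± 2.75 against 4.69 ± 0.486) and Xist lower (0.0063 ± 0.00584 against 1.67 ± 0.336). In limma 0 of 18 pan-endothelial, 30 cell cycle, 14 glycolysis, 13 erythroid, 16 neutrophil, 10 B lymphoid, 12 mitochondrially encoded, 5 Notch target (median -0.04, mean 0.16) and 7 poly(A)-less genes (median -0.14, mean 0.24) passed. The niche (3 up, 6 down of 19), VEGF (1 up of 9), p53 target (2 down of 20), stem (1 up of 13) and mural lists (1 down of 5, median 0.4, mean -0.13) were not called. The cell cycle list had a median of 0.02 and a mean of -0.01.

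Of 11889 genes, 890 passed, 338 higher and 552 lower (38% higher). For 27.8% of genes the groups did not overlap against 10% by chance. Without Apln+ replicate 1 the count was 3835, without Apln+ replicates 2 and 3 it was 311 and 482, and without diaphysis replicates 1, 2 and 3 it was 182, 166 and 149. TPM shifted the median gene by -0.15 and gave 27.2% higher calls. Scaling to the pan-endothelial genes shifted it by -0.33 and gave 474 calls. A minimum mean of 5 FPKM left 445.

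9Gy1D EC against Esm1+ EC compares irradiated endothelial cells with unirradiated cells marked by the Esm1-CreER allele, so that irradiation, allele and tamoxifen differ together. Esm1+ replicates 1 and 2 were nearly identical (chi-square per degree of freedom 1.39 over recovered reads), and n is 2 in Esm1+ EC if they are repeats of 1 sample. Stab2 was at 119 ± 67.6 in 9Gy1D EC against 2.83 ± 0.606 FPKM (log2 difference 4.8, SE 0.43, adjusted p = 0.00028), Fabp4 at 3780 ± 1460 against 56.5 ± 27.7 and the regulator of G protein signalling Rgs4 at 303 ± 138 against 0.502 ± 0.335. The stress hormone Gdf15 (32 ± 2.7 against 0.807 ± 0.591) and Cdkn1a (510 ± 28.9 against 59.5 ± 8.94) were higher as well. Esm1+ EC were higher in the cartilage collagen Col2a1 at 1270 ± 419 against 2.95 ± 2.17 (log2 difference -8.44, SE 0.47, adjusted p = 4.6e-05), Comp at 325 ± 147 against 0.788 ± 0.987 and Matn3 at 90.7 ± 38.7 against 0.0678 ± 0.117. The erythroid regulator Klf1 was at 181 ± 5.42 against 0.598 ± 0.152. Cartilage and erythroid RNA thus differ between the groups as well. Shares of other cells were not separated from differences within endothelial cells, for the lists below too. Col2a1 (ENSMUSG00000022483.17) lies on chromosome 15 from 97975602 to 98004695. Stab2 (ENSMUSG00000035459.18) on chromosome 10 from 86841198 to 87008025.

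In 9Gy1D EC 16 of 18 pan-endothelial, 8 of 9 sinusoidal, 19 of 22 p53 target, 18 of 20 interferon and 5 of 5 mural genes were higher, the same when adjusted over the list alone. Examples are Kdr (228 ± 100 against 31.4 ± 6.71 FPKM), Plk2 (297 ± 54.4 against 31 ± 11.5) and Ifit1 (124 ± 31.5 against 11.2 ± 2.99). Lower were 27 of 30 cell cycle (29 when adjusted over the list alone), 15 of 16 cholesterol synthesis and 13 of 14 glycolysis genes, among them Plk1 (12.6 ± 7.64 against 101 ± 5.47) and Tpi1 (42.6 ± 8.05 against 120 ± 10.6). These 8 lists had adjusted p = 3.3e-07, 3.5e-05, 2.2e-09, 5.7e-10, 0.00091, 3e-10, 1.2e-07 and 3.3e-05, and 0.35, 0.35, 0.18, 0.24, 0.25, 0.35, 0.24 and 0.35 with an estimated correlation. Also called up were the niche (10 up, 3 down of 18), VEGF (5 up, 1 down of 9), Notch target (2 up of 5), inflammatory (11 up, 2 down of 18), immediate early (8 up of 14) and megakaryocyte lists (4 up of 6), with estimated-correlation adjusted p = 0.35, 0.35, 0.51, 0.35, 0.35 and 0.51. Of these the VEGF and immediate early medians of 1.17 and 0.8 turned to -0.36 and -0.78 when scaled to the pan-endothelial genes.

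Beside them, 10 of 13 erythroid (12 when adjusted over the list alone), 11 of 16 neutrophil (12), 10 of 10 B lymphoid and 5 of 5 osteoblast genes were lower in 9Gy1D EC, with adjusted p = 1.2e-07, 5.9e-05, 2.8e-07 and 0.017, and 0.18, 0.42, 0.24 and 0.35 with an estimated correlation. Poly(A)-less RNAs were lower in 4 of 6 cases (adjusted p = 0.044, and 0.35 with an estimated correlation). Not called were the arterial (4 up, 2 down of 15), tip (6 up, 4 down of 16), matrix (5 up, 4 down of 15), monocyte and macrophage (6 up, 3 down of 12), mesenchymal (4 up, 2 down of 10) and mitochondrially encoded lists (5 up, 1 down of 12), whose medians of 0.42, 0.49, 0.55, 0.62, 0.79 and 0.31 turned to -1.02, -1.09, -0.85, -0.76, -1.99 and -1.3 under that scaling. The mesenchymal mean was -0.5 as deposited. Stem and progenitor genes (3 up, 8 down of 13) and sex-linked genes (0 of 3 passing in limma) were not called either. Of 11766 genes, 5150 passed, 2429 higher and 2721 lower. Groups lay apart for 57.4% of genes against 10% by chance. TPM shifted the median gene by 0.25 and gave 64.7% higher calls against 47.2%. Scaling to the pan-endothelial genes shifted it by -1.39 and gave 9348 calls, 4.02% of them higher. Without Esm1+ replicate 2 the count was 3429.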

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

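The splits of libraries, the thinning to LSK depth and the count of olfactory reads were planned before their results. The tests of the irradiation pattern and of the Apln pattern below were chosen only after the result was seen.

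The irradiation contrast and the Vav1 DTX contrast differed, by the test of the difference itself, at 3684 genes. In the comparisons 238 genes were called in opposite directions, such as Apln and the neutrophil gene Ctsg. These are fewer than independent lists would give, with 124 and 114 by direction against 368 and 265. For the 3684 genes, 1 of 100 drawn relabellings within the tables gave as many, the real one. The highest other gave 3614 and kept a real comparison. A count this high can thus come from 1 real comparison, and the relabellings cannot show that the contrasts differ. Chance is excluded only for labels mixed in both comparisons, since the 76 relabellings that kept neither gave at most 4. The 14 lists called in that difference were matched or exceeded in 24 of 100 relabellings, up to 19, so chance is not excluded for them. The 1854 genes higher in bone EC than in every blood group were reached by 1 of 100 splits (highest other 243). That excludes only randomly mixed labels. Mixed groups join unlike populations, which widens their spread, and the splits cannot tell population from library kit. The 1214 genes that moved the same way in both contrasts were reached by 1 of 100 relabellings (highest other 0), which decides nothing, since no other relabelling called a gene the same way in both.

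For the 8 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, so they cannot exclude chance. In Lin- against BMC, Vav1 DTX EC, Apln+ EC and 9Gy1D EC, 5 to 8 of 10 splits gave as many called lists, the real one included. Mixed labels thus also give list counts of that size. As many genes as the real split came from 1 split each: 8608, 8822, 9287, 3065 and 5150 genes in bone EC against LSK, Lin- and BMC, Vav1 DTX EC and 9Gy1D EC, with 0 as the highest other. It was 7144 in Lin- against BMC and 890 in Apln+ EC, with 1, and 5463 in irradiated bone EC, with 2. For called lists the splits with as many were 1 for LSK (17, highest other 16), 3 for Lin- (19 and 21), 1 for BMC (19 and 17), 7 for Lin- against BMC (9 and 17), 1 for irradiated bone EC (15 and 13), 8 for Vav1 DTX EC (9 and 19), 7 for Apln+ EC (10 and 13) and 5 for 9Gy1D EC (19 and 20).

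In irradiated bone EC the sinusoidal, p53 target and interferon lists were higher and blood cell lists lower. An equally smaller share of every blood cell type is argued against by the monocyte and macrophage median, which lies 3.11 above the highest of the other 3 blood lists on the log2 scale. The sinusoidal list also argues against a smaller share of blood RNA alone. It kept a mean difference of 0.85 (SE 0.13) after scaling to the pan-endothelial genes. The means of p53 targets (-0.16, SE 0.19) and interferon genes (-0.12, SE 0.17) lost their rise, as predicted for a smaller share. The scaling overcorrects genes that blood cells express too. Of p53 targets 5 of 19 and of interferon genes 10 of 20 were higher in bone EC than in every blood group. Whether a smaller share accounts for these means is therefore not decided. The members Cdkn1a (1.31) and Phlda3 (1.72) still passed under that scaling, and a larger share of sinusoidal cells among the endothelial cells may be part of it, since the sinusoidal list exceeded the arterial one by 1.47 after that scaling. A change of expression within cells after irradiation stays open and was not tested.

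Apln was at 0.419 to 1.24 FPKM in every library of Apln+ EC and diaphysis EC and at 1.87 to 66.2 in those of the other endothelial groups. The scaling of that table is argued against, since with all 33 libraries scaled together the lowest other endothelial group was still 3.42 times the higher of these. The Apln-CreERT2 allele stays open in Apln+ EC, which lie below the lowest other group by a factor of 3.31, since no other group carries it; the labels of diaphysis EC, which are low as well, name no such allele. In Apln+ EC 0 of 15 other tip genes lay below every endothelial group of the other tables. This does not decide whether tip and angiogenic cells are few there. A gene need only exceed 1 of these groups, and some list members are also expressed in marrow blood cells (Plaur, 363 FPKM in BMC). Few such cells stay open in diaphysis EC too, where 7 genes lay below, such as Col4a1 (15.5 FPKM, lowest other group 46.5). What lowers Apln stays open, and a change of its expression within cells was not tested.

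LSK libraries held more genes at 1 FPKM or more than any other group. Low depth is argued against, since the bone EC library with most such genes, thinned to the lowest LSK depth, still held 12896, against at least 14925 in LSK. Reads from outside expressed genes, such as genomic DNA, may account for it: 1247 olfactory receptor genes, not known to be active in blood cells, took at least 557 RPM in each LSK library and at most 18.2 elsewhere. No biological explanation was tested.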

How the results depend on the processing

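The replicate block, the filters, TPM and leaving out each library were planned; voom, scaling to the pan-endothelial genes, averaging Esm1+ replicates 1 and 2 and the block with an estimated correlation are tests chosen only after the result was seen.

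With pseudocounts of 0.1 and 5, no filter, median-of-ratios scaling and voom, the 12 counts of genes or lists stayed within 1.5 times their main value, as did 11 of 12 with TPM or the replicate block and 8 of 12 with a mean of at least 5 FPKM. Median-of-ratios scaling could change little, since the factors of the deposited values within a table ran from 0.982 to 1.035. Library sizes for voom were set the same way, so neither setting checks the scaling independently. Whether the replicate numbers pair the samples was not settled. In 0 of 8 comparisons did all pairs of equal number correlate above 0.1. Replicates 2 and 3 did so in the irradiation comparison (0.264 and 0.208), and replicates 1 and 3 in Apln+ EC against diaphysis EC (0.332 and 0.297). Pairs of unequal number reached 0.24 and 0.282 there. A mean of at least 5 FPKM, which tests fewer genes, gave 5083, 5624 and 6069 genes in bone EC against LSK, Lin- and BMC and 445 in Apln+ EC. TPM gave 13810 genes in bone EC against LSK, and the block gave 2399 in the difference of the irradiation and Vav1 DTX contrasts. Scaling to the pan-endothelial genes gave 9977, 1519, 474 and 9348 genes in irradiated bone EC, Vav1 DTX EC, Apln+ EC and 9Gy1D EC. Called lists fell from 131 over 9 contrasts to 1 with an estimated correlation and 0 with the block as well. With that correlation bone EC against LSK kept 8 lists under TPM, 9 with no filter and 0 with a mean of at least 5 FPKM, and 9Gy1D EC kept 3 under scaling to the pan-endothelial genes. The cause was not tested beyond what these settings do by construction.

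Leaving out 1 library, which also tests with fewer samples, gave 1124 to 4764 genes in Vav1 DTX EC (highest without DTX replicate 2), 149 to 3835 in Apln+ EC (highest without Apln+ replicate 1), 3429 to 4813 in 9Gy1D EC, 2408 to 4985 in the difference of the irradiation and Vav1 DTX contrasts, 585 to 1497 moving the same way in both and 735 to 1943 above all blood groups. Of 5538 values of named genes with 1 library left out, 485 no longer passed and 0 reversed.

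Under scaling to the pan-endothelial genes 85 of 497 named gene values no longer passed and 14 reversed: Nrp1 (-0.2), Hes1 (-0.22), Dll4 (-0.2), Slc2a1 (-0.21), Fosb (-0.1), Hspa1b (-0.08) and Dusp1 (-0.35) in irradiated bone EC, Atf3 (-0.02), Ier3 (-0.38), mt-Nd3 (-0.37), mt-Nd2 (-0.77), mt-Co3 (-1.03) and Ddx3y (-1.17) in 9Gy1D EC, and Insig1 (-0.15) in the difference of the irradiation and Vav1 DTX contrasts. The scaling lowers every gene where pan-endothelial genes rise. Scaling all 33 libraries together left 138 of 143 levels within 1 SD. With Esm1+ replicates 1 and 2 averaged, which leaves 2 Esm1+ samples, 3449 genes were called in 9Gy1D EC, and 10 of 108 named gene values and 1 of 27 lists no longer passed.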

Other observations

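The genes followed here were chosen after their values were seen, and no test was planned for them. Levels in different tables were normalized separately and were not tested against each other.

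Several genes with large differences in 1 or more comparisons can be followed across the endothelial groups. Fgf23 was at 263 ± 14.4 FPKM in irradiated bone EC, 33 ± 17.2 in 9Gy1D EC and 16.3 ± 6.3 in Vav1 DTX EC, against 5.29 ± 1.86 in bone EC, 1.86 ± 0.746 in Vav1 control EC and 8.26 ± 2.8 in diaphysis EC, and was listed at 0 in Esm1+ EC. Tmem252 was at 37.4 ± 14.4 in irradiated bone EC and 149 ± 170 in Vav1 DTX EC, with 0.847 ± 0.527 and 1.17 ± 0.409 in their controls, and at 5.06 ± 1.27 in 9Gy1D EC. Madcam1 was at 33 ± 10.8 and 72.5 ± 68.4 in those groups and 2.05 ± 1.45 and 1.99 ± 0.447 in the controls, but at 0.559 ± 0.487 in 9Gy1D EC. Saa3 was at 807 ± 1060 in Vav1 DTX EC and at 4.24 ± 2.24 in irradiated bone EC, and the metallothionein gene Mt2 at 517 ± 571 and 47.6 ± 72.2. In Vav1 DTX EC the spread of both exceeded the mean, as it did for Mt2 in irradiated bone EC (131, 6.7 and 5.13 per library, and 9.3 ± 3.55 in bone EC). Cxcl9, at 312 ± 56.6 in irradiated bone EC, was at 7.07 ± 4.61 in Vav1 DTX EC and 21 ± 3.93 in 9Gy1D EC.

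The collagen gene Col2a1 was at 1270 ± 419 FPKM in Esm1+ EC, 531 ± 266 in Lin- and 35.3 ± 37.8 in Apln+ EC, and at 0.438 ± 0.296 in bone EC. Comp followed with 325 ± 147, 64.2 ± 26.7 and 26.2 ± 33.6, and 1.26 ± 0.324 in bone EC. Adipoq was at 109 ± 8.76 in diaphysis EC, 49.8 ± 20.5 in bone EC, 53.1 ± 11.3 in Vav1 control EC and 5.36 ± 3.49 in Esm1+ EC. Epx, a granule peroxidase of eosinophils, was at 1030 ± 229 in Esm1+ EC, 336 ± 322 in Apln+ EC, 146 ± 19.3 in BMC and 8.66 ± 6.6 in irradiated bone EC. Sele was at 128 ± 42.5 in irradiated bone EC, 88.7 ± 20 in diaphysis EC and 82.5 ± 41.8 in 9Gy1D EC, and at 3.32 ± 2.42 in Apln+ EC and 3.82 ± 3.4 in Esm1+ EC.

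Xist, a transcript of the inactive X chromosome, was at 24.4, 23.3 and 0.0215 FPKM in BMC replicates 1 to 3. The Y-linked Ddx3y was at 0, 0.0471 and 17.5 there. Replicates 1 and 2 thus carry the pattern of female cells and replicate 3 that of male cells. Xist was at 0.012 or less in each Lin- library and at 8.43, 3.56 and 9.16 in those of bone EC. Esm1+ replicates 1 and 2 differed by a chi-square of 1.39 per degree of freedom over their recovered reads (Pearson r 0.9956 across genes, which are not independent replicates), against 27.01 and 28.57 for the other pairs of that group. If they are repeat libraries of 1 sample, n is 2 in each SD and p of Esm1+ EC. Erythroid globin Hbb-bs was at 73, 83.4 and 38900 FPKM in the Lin- libraries. The predicted gene Gm10800 was at 5280 to 8070 FPKM in LSK libraries and at 53.4 or less elsewhere.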
